A study of Mus musculus with 4 samples.

How the data were processed

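Single-cell RNA libraries were made from oviducts of ovariectomized mice, 14 days after surgery and 2 h after an injection of 0.25 µg E2 or of vehicle in 100 µL. Per the labels, each treatment was a pool of oviducts from 4 mice, cut into InfAmp and IsthUTJ before the cells were isolated, so the 4 libraries are 1 per treatment and region. Because both regions of a treatment come from the same animals, the regions were compared with the pool as a block. E2 and vehicle have a single pool each, and no p-value was computed for that comparison.

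The deposited files hold raw UMI counts per gene and cell barcode, made with Cell Ranger 6.0.1 per the file headers. The submitters' processing notes name the mouse build GRCm38 and the use of Scanpy 1.6.0. Barcodes had already been called as cells (lowest total 500 UMIs). The annotation release is not given in the sources used here, so positions of genes were read from GENCODE vM21 on the same build by gene identifier. A second copy of each table was identical and was not used. The 31253 genes include 91 that share their symbol with another identifier.

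The libraries vehicle InfAmp, vehicle IsthUTJ, E2 InfAmp and E2 IsthUTJ had 6857, 7603, 5901 and 5569 barcodes and a median of 5678, 4610, 6011 and 3957 UMIs. Cells with at least 500 genes and under 20% mitochondrial UMIs were kept, which left out 2746 of 25930 barcodes. Doublets were marked by Scrublet in each library with its automatic threshold. Where that threshold marked under 0.5% of cells, which happened in both InfAmp libraries (0.02% and 0.48%), the highest scores up to 0.8% per 1000 barcodes were taken instead. This removed 339, 169, 248 and 57 cells (5.48%, 2.46%, 4.72% and 1.17%) and left 5843, 6696, 5009 and 4823 cells, 22371 in all.

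Cells of all libraries were clustered together, with no correction between libraries, by Leiden at resolution 1 on 30 principal components of 2000 variable genes, with 15 neighbors and counts scaled to 10000 per cell. Each of the 27 clusters was named by the mean standardized score of 16 marker lists, written before the data were examined. A cluster stayed without a class if its best score was weak, if another class scored nearly as high, if it had few UMIs and no marker among its top 10 genes, or if those top genes held more markers of another class. This left 5 clusters unnamed. The thresholds of this naming rule for clusters were set after the data were opened. The tools were Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and scikit-image 0.26.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

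UMIs were summed per library and class. Ciliated, secretory and fibroblast cells are the main classes, with 1957, 160, 1609 and 142 ciliated cells, 2755, 2968, 2215 and 1707 secretory cells and 133, 1144, 240 and 981 fibroblasts in the library order above. Mesothelial cells, smooth muscle cells and macrophages also had at least 50 cells in every library and are described beside them. For E2 against vehicle, a gene counted as measured if its larger UMI sum was at least 30 and its larger CPM at least 20 in each region. It passed if it was at least 2-fold higher, or at least 2-fold lower, in both regions, with 0.5 UMIs added to each sum. CPM have exact Poisson intervals, shares exact binomial intervals, and ratios intervals from the binomial split of their counts. Folds against a group without UMIs are lower bounds against a floor of 3 counts.

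For InfAmp against IsthUTJ, edgeR 4.0.16 (limma 3.58.1, R 4.3.3) was used with quasi-likelihood tests, TMM scaling, the filterByExpr filter by region and a term for the pool, which left 1 residual degree of freedom. The median prior degrees of freedom were 11.45 in ciliated cells, 3.38 in secretory cells and 22.85 in fibroblasts. P-values were adjusted by Benjamini-Hochberg over the genes of a class. DESeq2 1.42.0 was run as an alternative.

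The named genes follow a rule: per main class, the 10 genes higher and the 10 lower with the largest smaller of both regions' ratios for E2, and the 8 genes with the largest fold each way for region, among those past the rule or test. For region, a gene was named only if its direction was the same in both pools. Mitochondrial, ribosomal protein and hemoglobin genes, Xist, unnamed gene models and genes under 10% of their level in the class where they are highest were passed over for naming, not for counting. Up to 4 members per list were named, and the receptors of the report always; the values of 1 further receptor are not reported here. Names outside the rule, such as the genes shared by several classes and those with opposite directions, were chosen after their values were seen.

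The comparisons, the size rule, the region test, the naming rule and 18 gene lists were fixed before the data were examined. The lists are early estrogen-induced genes of the rodent uterus, immediate early genes, heat shock genes, motile cilia genes, oviduct secreted products, sex steroid receptors and cofactors, inflammatory cytokines and NF-kB targets, interferon-stimulated genes, ion and water transport, contractility and its receptors, cell cycle, proteases and inhibitors, glucocorticoid-induced genes, circadian clock genes, extracellular matrix, growth factors and morphogens, region and Hox genes, and mitochondrially encoded genes. A list's median log2 ratio was placed among 10000 random lists matched on size and expression, as description. Lists with fewer than 5 measured members in a class are not reported there.

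Alternatives fixed in advance varied the cell filter, doublet removal, clustering resolution, scaling, low-count filter, fold, weighting of cells, thinning of every cell to 1000 UMIs, the block, the tool and each library left out. A doublet rate alike in every library and the use of only the ciliated cluster present in both regions were added after the data were seen.

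Both calculations were tested on simulated data. For E2 these held counting error only, with no variation between pools, libraries or clusters. For region they had the same dispersion for every gene and a pool effect alike in both regions. The false calls below therefore hold for these settings and do not measure those in the real data. The E2 rule recovered, among measured genes made 2.83-fold different, 93.0% in ciliated cells, 100.0% in secretory cells and 92.9% in fibroblasts, and called 0 unchanged genes. Of 100 fibroblast genes made 2.83-fold different only 56 reached the measured level. The region test recovered 57.1%, 70% and 25.5% of genes made 2-fold different and 88%, 100% and 75% of those made 4-fold different in ciliated cells, secretory cells and fibroblasts, with 8, 6 and 5 false calls.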

Results

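The question was how a single dose of 17β-estradiol (E2), the main ovarian estrogen, acts within 2 h on each cell type of the mouse oviduct, and whether its 2 ends respond alike. The oviduct was divided at the ampulla-isthmus junction into infundibulum plus ampulla (InfAmp), the end that takes up the egg, and isthmus plus uterotubal junction (IsthUTJ), the end next to the uterus. Each treatment was 1 pool of oviducts from ovariectomized mice, and both of its regions came from that same pool. There was 1 library per treatment and region, so E2 was compared with vehicle by size alone, with no test and no error between replicates. Intervals are 95% and cover counting error only.

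Ciliated epithelial cells, which move eggs and embryos with motile cilia, made up 33.5% of the cells of the vehicle InfAmp library and 32.1% of the E2 InfAmp library. In IsthUTJ they were 2.39% with vehicle and 2.94% with E2 (exact binomial intervals 2.04 to 2.78% and 2.49 to 3.46%). Secretory (non-ciliated) epithelial cells were 47.2% with vehicle and 44.2% with E2 in InfAmp, and 44.3% and 35.4% in IsthUTJ. Fibroblasts, the connective tissue cells, were 2.28% and 4.79% in InfAmp and 17.1% and 20.3% in IsthUTJ. Smooth muscle cells were 0.86% with vehicle and 3.95% with E2 in InfAmp, but 14.1% and 3.98% in IsthUTJ. Mesothelial cells, which line the outer surface, were 4.67% and 2.91% in InfAmp and 11.04% and 16.2% in IsthUTJ. Macrophages, monocytes and dendritic cells were 1.95% and 3.05% in InfAmp and 4.30% and 5.66% in IsthUTJ. Clusters that received no class held 8.69% (vehicle) and 7.63% (E2) of InfAmp cells and 3.35% and 7.69% of IsthUTJ cells. The ciliated share of IsthUTJ depended on the clustering and on the cells kept. On the same cells it was 3.87% with vehicle and 5.58% with E2 at resolution 0.5, and with no cell left out for few genes or mitochondrial RNA 3.98% and 6.22%.

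**Figure D1:**
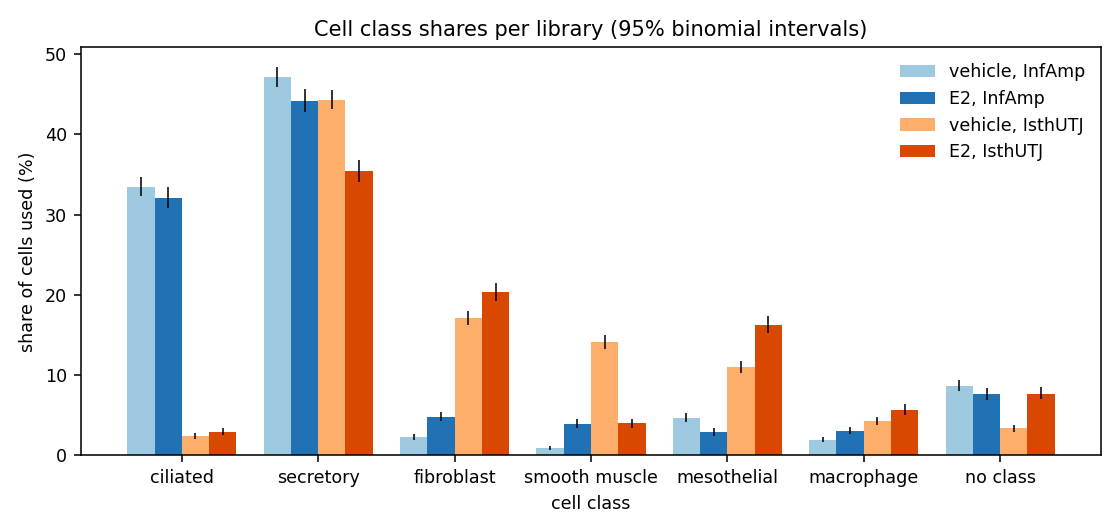
Share of the cells used in each library (percent, vertical axis) for 6 cell classes and for clusters without a class (horizontal axis), as bars with 95% binomial intervals per library. Ciliated cells stood at 33.5% and 32.1% in the InfAmp libraries against 2.39% and 2.94% in the IsthUTJ libraries.

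The receptor of the injected hormone, Esr1 (estrogen receptor alpha), was read in the epithelium and in the stroma. Esr1 stood at 140.2 CPM (UMIs per 1e6 UMIs of the class) with vehicle and 161 CPM with E2 in ciliated cells of InfAmp, and at 217 and 174 CPM in IsthUTJ. Secretory cells had 208 and 219 CPM in InfAmp and 291 and 253 CPM in IsthUTJ, and fibroblasts 283 and 230.4 CPM in InfAmp and 223 and 249.8 CPM in IsthUTJ (Poisson intervals 226 to 350 CPM and 194 to 272 CPM in InfAmp, 208 to 239 CPM and 233 to 268 CPM in IsthUTJ). Macrophages had 12.4 to 20.6 CPM. With every cell thinned to 1000 UMIs the order of E2 and vehicle turned in ciliated cells of IsthUTJ (150.0 CPM with vehicle, 211 CPM with E2) and in secretory cells of InfAmp (232 and 217 CPM), so no direction is drawn for Esr1 there. With vehicle, 54.8% of ciliated cells and 73.1% of secretory cells of InfAmp and 44.4% of fibroblasts had an Esr1 UMI, against 5.26% of the 19 T or NK cells of that library, taken as the background of free RNA. In IsthUTJ the shares with vehicle were 73.1% of ciliated cells, 85.3% of secretory cells and 45.0% of fibroblasts, against 3.23% of 93 T or NK cells. T or NK cells were shallower (median 1509 UMIs in vehicle InfAmp and 2106 in vehicle IsthUTJ) than ciliated cells (6175 and 8251 UMIs) and secretory cells (6393 and 8997 UMIs), and close to fibroblasts (1995 and 2547.5 UMIs). With every cell thinned to 1000 UMIs, the shares with vehicle in InfAmp were 11.5% of ciliated cells, 21.0% of secretory cells and 26.6% of fibroblasts, against 0% of T or NK cells, which allows up to 18.5%. In vehicle IsthUTJ they were 14.4%, 26.6% and 21.7%, against 0% of T or NK cells with an upper limit of 4.02%.

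Pgr, the progesterone receptor and a known target of estrogen, differed by class. In fibroblasts Pgr was 151 CPM with vehicle and 434 CPM with E2 in InfAmp (2.85-fold higher, interval 2.09 to 4.01), and 136 and 332 CPM in IsthUTJ (2.44-fold higher, interval 2.19 to 2.73). With cells thinned, 9.68% of vehicle and 35.6% of E2 fibroblasts of InfAmp had a Pgr UMI, and 9.49% and 28.7% in IsthUTJ. In secretory cells Pgr was 21.2 and 38.0 CPM in InfAmp and 64.8 and 104 CPM in IsthUTJ, short of 2-fold in each region. In ciliated cells it was 16.2 and 22.4 CPM in InfAmp and 38.3 and 46.5 CPM in IsthUTJ. T or NK cells held 0 to 4 Pgr UMIs per library. Esr2 (estrogen receptor beta) had 0 to 3 UMIs in any library of these 3 classes, and Gper1, a membrane estrogen receptor, was at most 2.77 CPM (secretory cells of vehicle IsthUTJ), so neither was detectable in most cells at this depth.

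**Figure D2:**
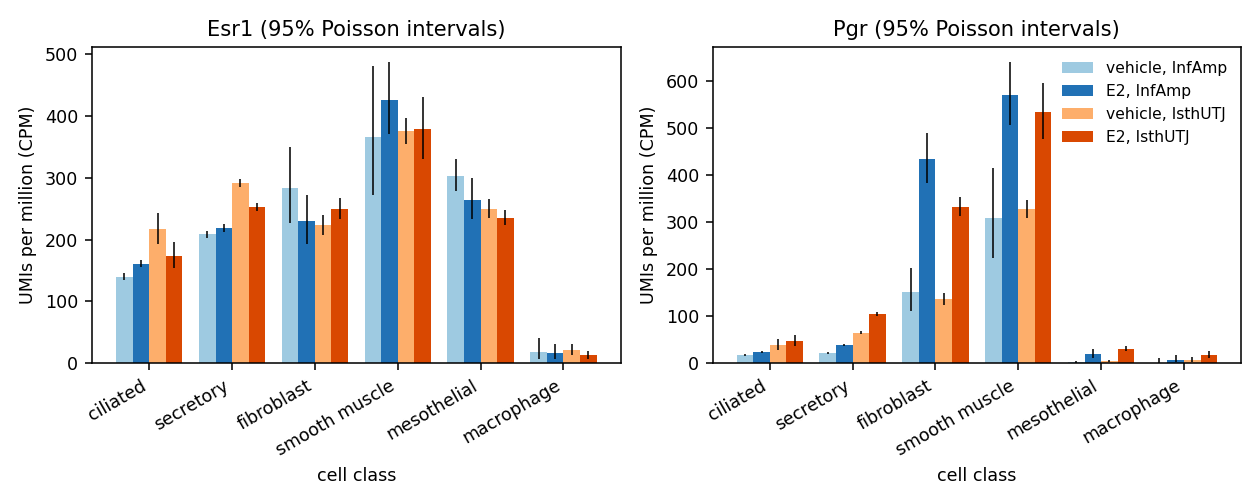
CPM of Esr1 (left) and Pgr (right) in 6 cell classes (horizontal axis), as bars per library with 95% Poisson intervals. Pgr in fibroblasts stood at 434 and 332 CPM in the E2 libraries against 151 and 136 CPM in the vehicle libraries.

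In ciliated cells, 2 h of E2 went with far higher levels of Klk1, which encodes a secreted serine protease (tissue kallikrein). Klk1 was at 0.41 CPM with vehicle and 53.9 CPM with E2 in InfAmp (124-fold, interval 64.0 to 330.3), and at 1.44 and 290 CPM in IsthUTJ (162-fold, interval 55.2 to 1661, from 2 vehicle UMIs). Aqp5, a water channel, was 16.5-fold higher in InfAmp (9.37 to 155 CPM) and 17.4-fold higher in IsthUTJ (20.2 to 357 CPM). Transcription factor genes followed: Sox18 was 16.2-fold higher in InfAmp and 52.2-fold (interval 17.5 to 537, from 2 vehicle UMIs) in IsthUTJ, Mycl 7.99-fold and 8.99-fold, and Stat5a, which relays cytokine signals, 6.80-fold and 11.01-fold. Mycn was 8.84-fold higher in InfAmp and 44.2-fold (interval 14.7 to 454.6, from 2 vehicle UMIs) in IsthUTJ. Among the genes lower with E2, Edn1 (endothelin, which contracts smooth muscle) was 3.51-fold lower in InfAmp and 8.56-fold lower in IsthUTJ, and Areg, a ligand of the EGF receptor, 2.94-fold and 9.16-fold lower. Inside cluster 4 alone, the ciliated cluster of both regions, Edn1 and Areg no longer passed the rule: the smaller of the 2 log2 ratios was -0.11 for Edn1 and -0.48 for Areg. Ccn2, a matrix protein gene, was 3.17-fold lower in InfAmp and 84.2-fold lower in IsthUTJ, where the E2 library held 1 UMI (interval 22.5 to 5093). Of 6490 measured genes, 81 were at least 2-fold higher and 13 at least 2-fold lower in both regions, where independent regions would share 4.3 and 0.4. Both regions of a treatment come from the same mice, so a difference between the pools appears in both, and the excess over these values, here and in the other classes, is not by itself an effect of E2. The other genes with the largest differences were Rapgefl1, Mad2l1, Slc7a5 and Jdp2 (higher, between 5.15-fold and 13.8-fold) and Rnf186, Hs3st1, Lratd1, Cdc42ep3, Peli3 and Prr15 (lower, between 2.18-fold and 7.79-fold). Prr18 was 3.44-fold lower in InfAmp and 18.55-fold lower in IsthUTJ, from 2 UMIs with E2 there (interval 6.02 to 197). In IsthUTJ all but 1 of the ciliated cells were in cluster 4, while those of InfAmp were in clusters 3, 9 and 4 (61.2%, 25.4% and 13.3% with vehicle, 55.5%, 32.2% and 12.3% with E2).

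Motile cilia genes differed little with E2 in ciliated cells: the median log2 ratio of E2 over vehicle of 24 measured genes was -0.07 in InfAmp and -0.06 in IsthUTJ, and none passed the 2-fold rule (Dnah5, a dynein of the cilium, at -0.14 and -0.48). Estrogen-induced genes known from the rodent uterus had medians of 0.40 and 0.56 over 16 genes, with 5 higher (Stat5a, Greb1, Vegfa and Cdkn1a among them), 1 lower (Areg) and 10 neither. Among 10000 random lists matched on expression these medians were at percentile 100.0, as rounded, in each region. Heat shock genes stayed near 0 (-0.03 and 0.03, 0 of 14 past the rule). Ion and water transport genes had medians of 0.355 and 0.335 over 7 genes, and Aqp5 alone passed the rule. Glucocorticoid-induced genes had medians of 0.02 and 0.55 over 6 genes, with Ddit4 and Cdkn1a higher. Mitochondrially encoded genes stood at 0.12 and 0.105 over 12 genes, with none past the rule. Immediate early genes, which respond within minutes to many stimuli and to tissue handling, had medians of -0.19 and -0.09, and none of 18 passed.

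Secretory cells shared the leading gene. Klk1 was at 1.95 CPM with vehicle and 128 CPM with E2 in InfAmp (64.9-fold, interval 49.3 to 89.2), and at 8.54 and 153 CPM in IsthUTJ (17.9-fold, interval 15.8 to 20.5). Nptx1, a secreted pentraxin known from neurons, was 36.2-fold and 15.8-fold higher, and Rapgefl1, a gene of a nucleotide exchange factor family, 15.3-fold and 12.9-fold. Greb1, a cofactor of the estrogen receptor and a classic estrogen target, was 45.0 and 314 CPM in InfAmp (6.97-fold higher) and 71.4 and 494 CPM in IsthUTJ (6.92-fold). Nrtn, a growth factor gene, was 81.0 and 431 CPM in InfAmp and 129 and 709 CPM in IsthUTJ. On the lower side, Lratd1 was 4.93-fold and 4.16-fold lower, Stc1 (stanniocalcin, a secreted hormone) 3.31-fold and 4.06-fold, the homeobox gene Dlx5 3.24-fold and 7.85-fold, and Edn1 3.13-fold and 10.3-fold. Of 5616 measured genes, 159 were at least 2-fold higher and 31 lower in both regions, where independent regions would share 11.3 and 1.0. The rest of the largest were Eva1a, Mtss2, Espn, Ppargc1b and Aqp5 (higher, between 5.71-fold and 11.6-fold) and Arid5b, Ccn2, Prr15, Epha4, Dync1i1 and Plpp3 (lower, between 2.70-fold and 13.95-fold). With cells thinned to 1000 UMIs, Dync1i1 no longer passed the rule. The clusters behind the class differed with treatment: InfAmp secretory cells were in clusters 0 (48.4%) and 2 (49.8%) with vehicle and 1 (39.2%) and 2 (57.4%) with E2. Those of IsthUTJ were in clusters 25 (45.7%), 21 (34.1%), 0 (11.6%) and 18 (7.8%) with vehicle, and 5 (67.3%), 18 (18.9%) and 1 (13.1%) with E2.

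The uterine estrogen-induced genes had medians of 0.72 and 0.71 over 14 genes in secretory cells, with 5 higher, 1 lower and 8 neither (Greb1, Stat5a, Vegfa and Cdkn1a the highest). Immediate early genes had medians of 0.07 in InfAmp and 0.76 in IsthUTJ over 18 genes, with none past the rule in both regions. Oviduct secreted products had medians of -0.14 and -0.26 over 8 genes, with 1 higher: Tgfb2, a growth factor of the TGF family, at 1.57 and 2.59, beside Ovgp1, the oviduct glycoprotein, at -0.37 and -0.28. Proteases and their inhibitors had medians of -0.04 and 0.09 over 9 genes, with Klk1 and Tmprss2 higher. Among 8 ion and water transport genes, Aqp5 was higher and the potassium channel Kcnn4 lower (-1.59 and -1.43). Circadian clock genes had medians of -0.30 and -0.10 over 7 genes, with Arntl higher (1.70 and 2.16). Interferon-stimulated genes had medians of -0.07 and 0.09 over 6 genes, with none past the rule.

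In fibroblasts Pgf, placental growth factor, was 19.7 CPM with vehicle and 322 CPM with E2 in InfAmp (15.5-fold, interval 7.36 to 45.0), and 15.2 and 476 CPM in IsthUTJ (31.0-fold, interval 23.9 to 41.8). Wnt4, a signal needed for female tract development, was 72.4 and 758 CPM in InfAmp (10.3-fold) and 89.3 and 1272 CPM in IsthUTJ (14.2-fold). Ptges, a prostaglandin E synthase, was 11.5-fold and 17.6-fold higher. Inhbb, a subunit of activin, was 24.7-fold higher in InfAmp (interval 7.75 to 239.6, from 2 vehicle UMIs) and 10.7-fold in IsthUTJ. Fam78b had 0 UMIs with vehicle in InfAmp and 45 with E2, at least 7.61-fold higher against a floor of 3 counts in that library, and was 11.3-fold higher in IsthUTJ. Lower with E2 were transcription factors that respond early to stimuli: Klf2 was 1293 and 147 CPM in InfAmp (8.75-fold lower) and 1410 and 259.7 CPM in IsthUTJ (5.43-fold lower), Atf3 3.64-fold and 2.92-fold lower, and Klf4 3.77-fold and 2.79-fold lower. Of 3215 measured genes, 163 were at least 2-fold higher and 21 lower in both regions, where independent regions would share 26.2 and 0.7. In InfAmp the E2 fibroblasts held 599047 UMIs and the vehicle ones 303886. Genes high with E2 thus reached the measured level of 30 UMIs at a lower CPM, which favours higher over lower genes. With no low-count filter 871 were higher and 304 lower. The median gene stood at 0.165 (InfAmp) and 0.117 (IsthUTJ) on the log2 scale. Centred on it, 132 genes were higher and 29 lower. The rest of the largest were Pqlc3, Caskin2, Gpr146, Mad2l1 and Dennd2a (higher, between 8.47-fold and 15.9-fold, with 1 to 12 vehicle UMIs in InfAmp) and Ly6h, Klf6, Gem, Cebpd, Ccl11, Hlf and Dnajb1 (lower, between 2.46-fold and 4.03-fold). Vehicle fibroblasts were in clusters 11 (51.1% in InfAmp, 79.9% in IsthUTJ) and 14 (46.6% and 19.3%). E2 fibroblasts were in clusters 12 (55.4% and 67.6%) and 14 (42.1% and 3.5%), and in IsthUTJ also in cluster 26 (26.3%).

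The uterine estrogen-induced genes were high in this class: their median was 1.55 in InfAmp and 1.00 in IsthUTJ over 15 genes (1.39 and 0.885 after centring), with 7 higher (Inhbb, Wnt4, Vegfa and Greb1 the highest), 1 lower (Klf4) and 7 neither. Immediate early genes had medians of -0.95 and -0.555 over 17 genes (-1.115 and -0.67 after centring), at percentile 0.0 of the random lists, as rounded. Of them 0 were higher, 4 lower (Klf2, Klf6, Atf3 and Nr4a1) and 13 neither. Inside cluster 14, the only fibroblast cluster with at least 30 cells in every library, the median was -1.157 in InfAmp but 0.111 in IsthUTJ. In IsthUTJ 34 E2 cells were in it. The medians of this cluster are over 18 genes, at the looser level of 10 UMIs and 5 CPM. Heat shock genes stood at -0.30 and -0.18, with Dnajb1 lower among 13. Extracellular matrix genes had medians of 0.135 and 0.26 over 14 genes, and after centring the InfAmp median was -0.03. Thbs1 alone among them was lower in both regions (-1.19 and -1.93). Growth factors and morphogens had medians of 0.20 and 0.80 over 8 genes (0.04 and 0.68 after centring), with Wnt4, Vegfa and Tgfb2 higher. Sex steroid receptors and cofactors had medians of 0.16 and 0.12 over 7 genes, with Nrip1, a corepressor of the estrogen receptor, and Pgr higher, and near 0 after centring (-0.001 and 0.002). Contractility genes and their receptors had medians of 0.34 and -0.54 over 5 genes, with Oxtr, the oxytocin receptor, higher (1.28 and 1.49). Of 13 proteases and inhibitors, none passed.

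**Figure D3:**
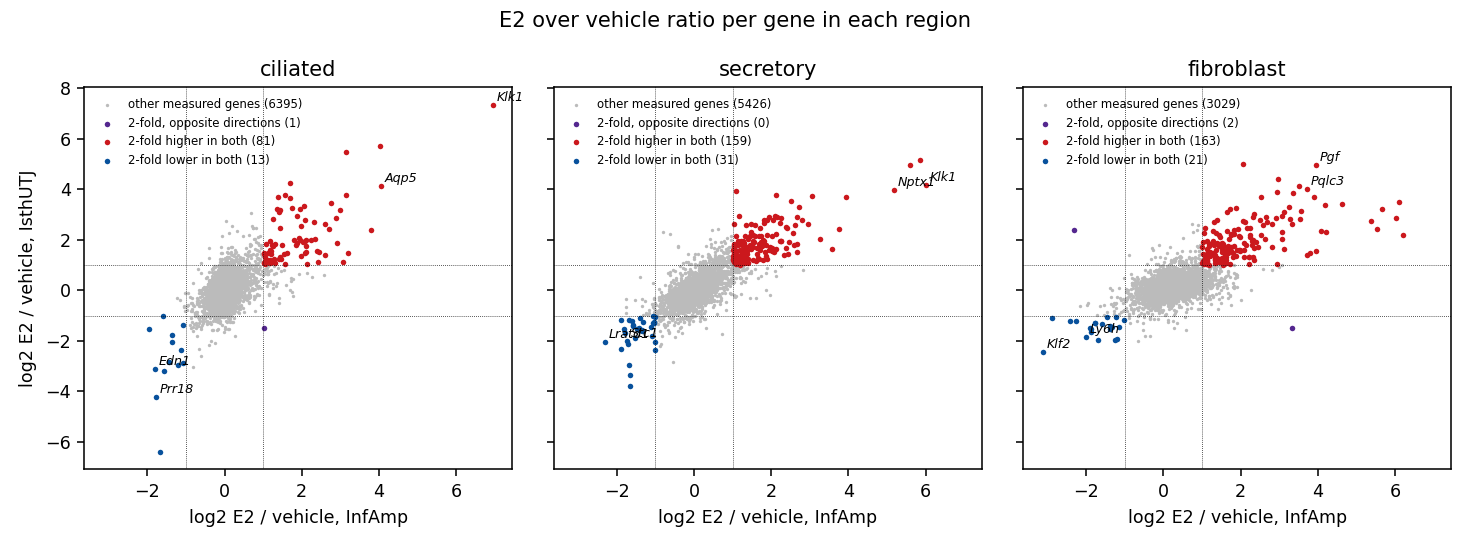
Log2 ratio of E2 over vehicle in InfAmp (horizontal axis) and IsthUTJ (vertical axis) for each measured gene in ciliated cells, secretory cells and fibroblasts, with dotted lines at 2-fold. Points past 2-fold in both regions lie mainly at upper right, with 81, 159 and 163 genes higher and 13, 31 and 21 lower.

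**Figure D4:**
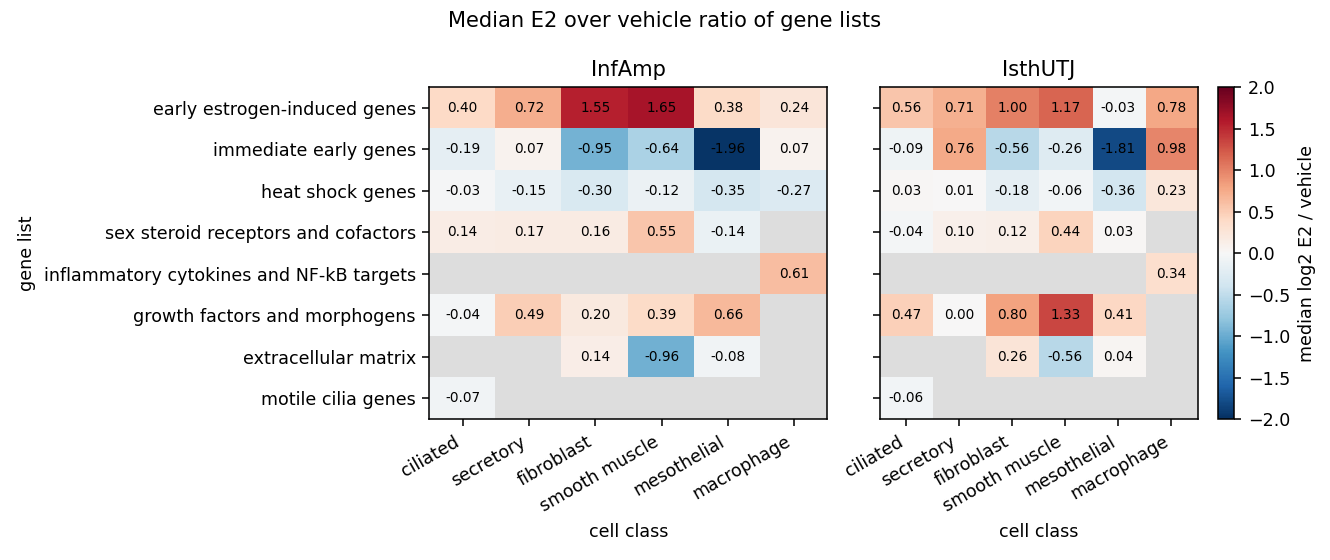
Median log2 ratio of E2 over vehicle of 8 gene lists (vertical axis) in 6 cell classes (horizontal axis) in each region, as colours with the value in each cell; grey marks lists with fewer than 5 measured genes. Immediate early genes stood at -0.95 and -0.56 in fibroblasts and at 0.07 and 0.76 in secretory cells.

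A small core of genes was higher with E2 in several classes. Ciliated and secretory cells shared 50 of the genes higher by the rule (1.6 for independent classes), fibroblasts and secretory cells 23 (1.6), and ciliated cells and fibroblasts 16 (1.0). All classes come from the same 4 libraries, so these overlaps are not independent of what the libraries share. B4galt5, Greb1, Mad2l1, Nrip1, Plekhg3, Tlnrd1 and Zmiz1 were higher in ciliated, secretory, fibroblast, smooth muscle and mesothelial cells alike, 7 genes in 5 of the 6 classes described. Zmiz1, a coregulator of nuclear receptors, was 2.71-fold and 5.51-fold higher in ciliated cells, 4.71-fold and 6.27-fold in secretory cells and 6.39-fold and 6.45-fold in fibroblasts. Arid5b and Tsc22d1 were lower in 4 classes. The names in this paragraph that are not among the largest of a class were chosen after their values were seen.

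Across genes, which are not independent replicates, the Pearson correlation of the log2 ratios of InfAmp and IsthUTJ was 0.61 in ciliated cells, 0.78 in secretory cells and 0.67 in fibroblasts. By rank (Spearman) it was lower, at 0.37, 0.7 and 0.51. Opposite 2-fold differences were rare: Cdk5r1 in ciliated cells (2.02-fold higher in InfAmp, 2.84-fold lower in IsthUTJ), 0 genes in secretory cells, and Tnfrsf12a and the unnamed gene model Gm26802 in fibroblasts. Tnfrsf12a, a receptor of the TNF family, was 10.1-fold higher in InfAmp (interval 3.05 to 99.2, from 2 vehicle UMIs) and 2.81-fold lower in IsthUTJ, and Gm26802 was 4.98-fold lower and 5.15-fold higher. These names were chosen after their values were seen. Secretory cells had 133 genes at least 2-fold higher and 66 lower in IsthUTJ and not in InfAmp, and 58 higher and 26 lower in InfAmp and not in IsthUTJ. In ciliated cells these were 142 and 106 in IsthUTJ alone and 43 and 6 in InfAmp alone. Fibroblasts had more in InfAmp alone (178 and 30) than in IsthUTJ alone (82 and 22). In ciliated cells and fibroblasts the region with more such genes had far fewer UMIs: 1384792 (vehicle) and 1526380 (E2) in IsthUTJ ciliated cells against 17188240 and 17929905 in InfAmp, and 303886 and 599047 in InfAmp fibroblasts against 3550080 and 3234317. Counting noise is larger there, so these counts do not rank the regions. Whether the response differed between the regions was not tested, since 4 libraries leave no degrees of freedom for it.

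The regions themselves could be tested, with each pool of mice as a pair. At an adjusted p under 0.05 (edgeR, 2 pairs), 1892 genes were higher and 2264 lower in InfAmp than in IsthUTJ in ciliated cells (13398 tested), 1903 and 2180 in secretory cells (14014 tested), and 151 and 241 in fibroblasts (10390 tested). These counts rest on 1 residual degree of freedom and on spread shared across genes. The 2 pools also differed in treatment. The spread between the pairs therefore includes any difference between the regions in the response to E2, and is not that of mice treated alike. Which direction held more genes depended on the setting: with no low-count filter 2466 genes were higher and 2149 lower in ciliated cells, and without the block for the pool 647 and 569 in secretory cells and 2 and 0 in fibroblasts. Leaving out vehicle InfAmp, vehicle IsthUTJ, E2 InfAmp or E2 IsthUTJ, with no pairs, left 731, 1839, 840 and 1902 genes in ciliated cells and 0, 499, 0 and 965 in secretory cells. In fibroblasts it left 0, 63, 0 and 94. Where edgeR called 0 genes, 2222 and 2589 genes in secretory cells and 586 and 782 in fibroblasts had an unadjusted p under 0.05, and DESeq2, with all 4 libraries, called 2932 and 93.

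Ciliated cells differed between the ends. Serpinb11 (a serine protease inhibitor family gene), Ptpru (a receptor phosphatase) and Bpifa3 had 2805, 1830 and 1404 UMIs in InfAmp and 0 in IsthUTJ, which made them at least 77.5-fold, 50.6-fold and 38.8-fold higher in InfAmp against a floor of 3 counts over both IsthUTJ libraries. Frmpd1os, Prkar2b, Wt1os, Mfsd4b1 and Trpc4 were also at 0 in IsthUTJ and at least 11.5-fold to 33.9-fold higher in InfAmp. Krt17, a keratin of stressed and basal epithelia, was 1.11 CPM in InfAmp and 232 CPM in IsthUTJ (log2 -7.83, SE 0.206, adjusted p 1.37e-10, same direction in 2 of 2 pools, as the naming rule requires). Plaur, the urokinase receptor, was 0.68 and 71.1 CPM, and Krt4 0.48 and 41.2 CPM. Serpina11, Asgr1, Thsd7b, Lipg and Vsnl1 were lower in InfAmp with 1 to 3 UMIs there (Serpina11 157-fold, counting interval 39.3 to 1363). Plaur, Lipg and Trpc4 stood at 26.6%, 20.7% and 18.2% of their level in their highest class, so free RNA and doublets can add to them. Of 25 motile cilia genes tested, 16 were higher in InfAmp, 0 lower and 9 neither (17 and 0 adjusted over the list alone), with Dnah5 at 1.29 and Hydin at 1.24 on the log2 scale. Of 12 mitochondrially encoded genes, 0 were higher and 7 lower (0 and 7 adjusted over the list alone), with a median of -0.19. Of 19 immediate early genes, 1 was higher and 17 lower (1 and 17 adjusted over the list alone), with Atf3 at -2.96 and Egr3 at -2.98. In other classes 0 were higher and 17 lower of 19 in mesothelial cells, and 0 and 6 of 19 in fibroblasts. Secretory cells had 2 higher and 3 lower of 19, smooth muscle 0 and 2 of 18, and macrophages 2 and 0 of 19. These genes also respond to tissue handling, which was not separated from region. Of 16 interferon-stimulated genes, 1 was higher and 11 lower (1 and 13 adjusted over the list alone), with Bst2 at -3.45. Wt1, a transcription factor of the urogenital ridge, was 267 CPM in InfAmp and 28.9 CPM in IsthUTJ (log2 3.10, SE 0.192). Foxa2 was 102 and 2.06 CPM. Pax2 was 9.37 and 83.5 CPM. Markers of other classes were lower in InfAmp ciliated cells too: 15 of 19 secretory markers (1 higher, median -1.53), 8 of 13 fibroblast markers (median -3.00) and 7 of 10 smooth muscle markers (17, 9 and 7 adjusted over the list alone, with Tagln at 3.93 and 60.5 CPM). Free RNA and doublets can give such differences, and they were not separated here. Within cluster 4 alone, which holds the IsthUTJ ciliated cells, 985 genes were higher and 1313 lower in InfAmp. Of the 16 genes named by rank for this class, 6 were tested there (Ptpru, Bpifa3, Frmpd1os, Krt17, Serpina11 and Plaur), all called in the same direction. The other 10 had too few counts, and the lists were not run there, so whether these hold within that cluster is not shown.

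Secretory cells differed between the ends too. Crabp2, which carries retinoic acid, was 0.11 CPM in InfAmp and 82.5 CPM in IsthUTJ (log2 -9.47, SE 0.389, adjusted p 0.00217, same direction in 2 of 2 pools, as the naming rule requires), and Slc25a48, a mitochondrial carrier gene, 0.57 and 197 CPM (log2 -8.30). Lrp2, an endocytic receptor, was 351-fold lower in InfAmp from 3 UMIs there (counting interval 119.8 to 1705). Sult4a1, Clca1, Lrfn5, Fam3b and Sval2 had 0 UMIs in InfAmp and were at least 21.6-fold to 53.7-fold lower. On the InfAmp side, Dcpp2, a secreted salivary-type protein gene, was 26.0 CPM against 0.04 CPM (656-fold, counting interval 181 to 5425, from 2 UMIs in IsthUTJ). Frmpd1os, Tnfrsf11b, Dner and Glb1l3 had 0 UMIs in IsthUTJ and were at least 24.0-fold to 103.7-fold higher, followed by Foxs1, Scara3 and Atp6v1b1. Frmpd1os, highest in ciliated cells, stood at 17.5% of its level there. Tnfrsf11b, Foxs1 and Scara3 were at 11.1%, 15.3% and 10.2% of their highest class, and on the lower side Sult4a1 and Lrp2 at 19.2% and 13.5%. Free RNA and doublets can add to such genes and were not separated. Of 14 growth factors and morphogens, 2 were higher and 5 lower in InfAmp (2 and 6 adjusted over the list alone). Wnt7a was 0.20 and 29.7 CPM (log2 -7.17, SE 0.317) and Ihh, Indian hedgehog, 0.45 and 20.2 CPM (log2 -5.60). Pgr was 28.6 CPM in InfAmp and 80.7 CPM in IsthUTJ (log2 -1.66, SE 0.104, adjusted p 0.00299). Of 18 interferon-stimulated genes, 0 were higher and 12 lower in InfAmp (0 and 15 adjusted over the list alone), with Irgm1 at -2.49. Of 14 inflammatory cytokines and NF-kB targets, 0 were higher and 7 lower (0 and 7 adjusted over the list alone), with Cxcl2 at -3.14. Macrophage markers were lower too (5 of 10, 1 higher, the same adjusted over the list alone, median -1.30), and so were 4 of 13 fibroblast markers (4 adjusted over the list alone). Free RNA and doublets of these cells were not separated here. All 12 mitochondrially encoded genes were lower in InfAmp (12 adjusted over the list alone), with a median of -0.48. Of 17 cell cycle genes, 0 were higher and 6 lower (0 and 6 adjusted over the list alone). Lcn2, lipocalin, was 539 CPM in InfAmp and 30.0 CPM in IsthUTJ. Of 25 motile cilia genes, 18 were higher and 1 lower in InfAmp (18 and 2 adjusted over the list alone), at levels such as 39.9 CPM for Ccdc153, which free RNA and doublets of the many ciliated cells there can give.

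Among the genes that differed in fibroblasts were Hox genes, which set position along the tract. Hoxa10 was 1.11 CPM in InfAmp and 37.4 CPM in IsthUTJ (33.8-fold, counting interval 6.01 to 1340.0, from 1 UMI in InfAmp), and Hoxa11 had 0 UMIs in InfAmp and 93 in IsthUTJ, at least 4.13-fold lower in InfAmp. Of 10 genes of the region and Hox list, 0 were higher and 4 lower (0 and 5 adjusted over the list alone), with Hoxd9 at -2.04 and Wt1 at -1.32. Mafk, a small Maf transcription factor, had 0 and 370 UMIs, at least 16.4-fold lower in InfAmp, and Iqcn, Mir17hg, Coch and Agtr2 were also at 0 there. Slc6a2, the noradrenaline transporter, was 1.11 and 47.3 CPM. Cpxm2, a carboxypeptidase-like matrix gene, was 111 CPM in InfAmp and 11.1 CPM in IsthUTJ (log2 3.22, SE 0.276, adjusted p 4.35e-08, same direction in 2 of 2 pools, as the naming rule requires), and Ptpre was 57.6 and 4.57 CPM (log2 3.29). Tmem178, Ndst3, Fhit, Cacna1d, Kcnq3 and Moxd1 were higher in InfAmp as well, between 5.69-fold and 15.8-fold. Ptpre, Fhit and Mafk stood at 22.0%, 10.1% and 32.4% of their level in their highest class, so free RNA and doublets can add to them. Of 12 inflammatory cytokines and NF-kB targets, 0 were higher and 7 lower (0 and 9 adjusted over the list alone), with Ccl2 at -3.74. Of 6 macrophage markers 2 were lower and 0 higher (2 and 0 adjusted over the list alone), with a median of -0.96. Of 10 sex steroid receptors and cofactors, 0 passed in either direction (0 and 0 adjusted over the list alone), and Esr1 was at -0.02 (SE 0.199). Ciliated cell markers were higher in InfAmp fibroblasts too (11 of 12, 12 adjusted over the list alone, with Ccdc153 at 113 and 3.39 CPM), which free RNA of the epithelium or doublets can give; these were not separated.

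On the mouse genome build GRCm38, with GENCODE vM21 as annotation, these genes lie as follows, all protein coding. Klk1 is on chromosome 7 from 44225360 to 44229618. Greb1 is on chromosome 12 from 16670615 to 16800886. Aqp5 is on chromosome 15 from 99590782 to 99594829. Pgf is on chromosome 12 from 85166635 to 85177790. Wnt4 is on chromosome 4 from 137277489 to 137299726. Klf2 is on chromosome 8 from 72319033 to 72321656. Esr1 is on chromosome 10 from 4611593 to 5005614, and Pgr on chromosome 9 from 8899833 to 8968611. Krt17 is on chromosome 11 from 100256217 to 100261029. Crabp2 is on chromosome 3 from 87948666 to 87953376, and Hoxa10 on chromosome 6 from 52231197 to 52240854. The libraries read the 3' ends of transcripts, so a UMI was assigned to a gene and not to a position within it.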

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

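The tests in this part were chosen after the results were seen. For the lower median of immediate early genes with E2 in fibroblasts, the handling-stress prediction was written after its value was known. The prediction on cluster mix was first written for both regions jointly and was split by region after its result was seen. The other predictions were written before their tests were run.

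The median of the immediate early genes was below 0 with E2 in fibroblasts in both regions, with 4 of 17 genes lower by the rule and 13 neither. Their medians were also below 0 in mesothelial cells (-1.96 and -1.81), smooth muscle (-0.635 and -0.263) and ciliated cells (-0.187 and -0.092). In macrophages the medians were 0.066 in InfAmp and 0.984 in IsthUTJ. In secretory cells they were 0.071 in InfAmp and 0.761 in IsthUTJ, which speaks against handling stress alike in every class, while stress that differed by class was not tested and stays open. With cells thinned to the same UMIs, at least 80.6% of the median was kept, which speaks against the weighting of cells by depth. Thinning leaves the expected CPM of each cell unchanged, so it cannot decide on other effects of depth. Inside cluster 14, the only fibroblast cluster with at least 30 cells in every library, 18 genes were measured at 10 UMIs and 5 CPM. Their median was -1.157 in InfAmp, which speaks against a different mix of clusters there. In IsthUTJ the median inside that cluster was 0.111, what a different mix of clusters would give, so the difference in IsthUTJ may be one of cluster mix, with only 34 E2 cells in the cluster and clusters formed on the same expression.

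The 7 genes higher with E2 in 5 of the 6 classes were tested for free RNA and for scaling. Their summed CPM in macrophages was higher by at most 16.7% of the median increase in the 5 classes (upper limit 23.2%). Macrophages were the class left out for all 7, so a gene 2-fold higher there too would not be in the set. A small rise in macrophages was thus largely fixed by the choice of genes, and the test cannot decide on free RNA. After centring on the median gene, 7 of 7 were still at least 2-fold higher in all 5 classes, which speaks against scaling. Treatment and pool of mice cannot be told apart with 1 pool each.

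Of the 199 secretory genes at least 2-fold different with E2 in IsthUTJ and not in InfAmp, 15.1% (10.4 to 20.8%) differed at least 2-fold between the main vehicle clusters 25 and 21 in the direction that fewer cells of 25 would give, against 9.7% and 9.4% of the genes lower and higher in both regions. The E2 library held 1 cell of cluster 25 and 3 of cluster 21, so this contrast gives no direction for a different cluster mix. The test is void, and a different mix stays open. With thinning 85.9% were still at least 2-fold different, which speaks against the weighting of cells by depth. On other effects of depth thinning cannot decide, as above.

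Some differences between regions were not tested for a cause. The E2 minus vehicle difference in the share of smooth muscle cells was 3.09 points in InfAmp and -10.12 points in IsthUTJ, 13.21 points apart. That of mesothelial cells was -1.76 and 5.19 points, 6.95 points apart. Genes at least 2-fold in opposite directions in the regions were 1 in ciliated cells (Cdk5r1), 2 in fibroblasts (Gm26802 and Tnfrsf12a), 3 in macrophages (Cxcl9, Cbr2 and Retnla) and 1 in smooth muscle (Gm26802). The median log2 ratio of mitochondrially encoded genes in macrophages was 0.689 apart between the regions (-0.17 in InfAmp, 0.52 in IsthUTJ). Clusters without a class held 7.69% of the E2 IsthUTJ cells and were not analysed further. The largest of these, cluster 22, carried mural cell genes such as Rgs5 and held 4.21% of them against 1.52% with vehicle.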

How the results depend on the processing

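The doublet rate alike in every library and the ciliated cluster of both regions alone were chosen after results were seen. The cause was not tested for any shift given here.

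The ciliated share of vehicle InfAmp (33.49%) was 40.48% at resolution 0.5, 37.6% at resolution 2.0, 36.83% with doublets by rate and 35.59% with stricter cells. That of E2 InfAmp (32.12%) was 39.09%, 35.52%, 34.66% and 34.46% in the same settings, and 30.73% with no cell filter. That of vehicle IsthUTJ (2.39%) was 3.87% at resolution 0.5, 3.98% with no cell filter, 3.87% with doublets kept, 3.77% with doublets by rate and 3.03% with stricter cells. That of E2 IsthUTJ (2.94%) was 5.58%, 6.22%, 5.51%, 5.47% and 3.55% in these settings, and 5.58% at resolution 2.0. The fibroblast share with stricter cells was 1.33% in vehicle InfAmp (2.28%), 14.81% in vehicle IsthUTJ (17.08%) and 3.32% in E2 InfAmp (4.79%), and with no cell filter 18.76% in E2 IsthUTJ (20.34%). The secretory share of vehicle InfAmp (47.15%) was 48.79% at resolution 0.5, 42.28% with no cell filter, 45.21% with doublets kept and 48.83% with stricter cells. With no cell filter it was 41.61% in vehicle IsthUTJ (44.32%), 39.2% in E2 InfAmp (44.22%) and 28.48% in E2 IsthUTJ (35.39%). With stricter cells it was 46.86% in E2 InfAmp and 31.23% in E2 IsthUTJ.

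The counts of genes higher and lower with E2 move by construction with the low-count filter, the fold and the depth. In ciliated cells (81 higher, 13 lower) they were 135 and 31 at 10 UMIs and 5 CPM, 504 and 229 with no low-count filter, 183 and 60 at 1.5-fold, 32 and 3 at 3-fold, 20 and 3 with cells thinned to 1000 UMIs, and 123 and 53 in the shared cluster alone. In secretory cells (159 and 31) they were 261 and 73, 902 and 569, 341 and 121, and 55 and 8 in the first 4 of these settings. In fibroblasts (163 and 21) they were 303 and 63, 871 and 304, 315 and 54, 74 and 4, and 55 and 11 when thinned. Opposite genes in ciliated cells (1) were 0 at resolution 0.5, 4 at 10 UMIs and 5 CPM, 312 with no low-count filter, 5 at 1.5-fold, 0 at 3-fold, 0 by the mean of CPM per cell and 0 when thinned. In secretory cells (0) they were 3 at 10 UMIs and 5 CPM, 567 with no low-count filter, 8 at 1.5-fold and 1 when thinned. In fibroblasts (2) they were 8, 497 and 12 in the same settings, 1 at 3-fold and 0 when thinned. After centring, 2 lists instead of 4 had a negative median in both regions in ciliated cells. Of the 60 named genes for E2, 33 were still measured with thinning, 55 with stricter cells and 59 with doublets kept or at resolution 0.5, and for the others no direction was read there. In the shared ciliated cluster 19 of the 20 ciliated ones were measured. None of those measured left its direction, and Edn1 and Areg in the shared ciliated cluster and Dync1i1 in thinned secretory cells no longer passed the rule.

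With cells thinned to 1000 UMIs, Esr1 with vehicle and E2 was 128.26 and 131.76 CPM in InfAmp and 150.0 and 211.27 CPM in IsthUTJ in ciliated cells. It was 306.45 and 231.11 CPM in InfAmp and 251.57 and 265.14 CPM in IsthUTJ in fibroblasts, and 232.26 and 217.17 CPM in InfAmp and 312.54 and 253.01 CPM in IsthUTJ in secretory cells. Pgr was 9.71 and 19.27 CPM in InfAmp and 31.25 and 42.25 CPM in IsthUTJ in ciliated cells. It was 129.03 and 511.11 CPM in InfAmp and 109.22 and 371.61 CPM in IsthUTJ in fibroblasts. In secretory cells Pgr was 30.36 and 37.26 CPM in InfAmp and 69.53 and 85.54 CPM in IsthUTJ. The secretory intervals overlapped in InfAmp (24.18 to 37.63 and 29.63 to 46.24 CPM) and in IsthUTJ (60.32 to 79.75 and 72.05 to 100.83 CPM). Those of ciliated cells overlapped too (5.85 to 15.16 and 13.09 to 27.35 CPM in InfAmp, 10.15 to 72.93 and 15.51 to 91.97 CPM in IsthUTJ). With thinning, E2 and vehicle changed order for Esr1 in ciliated cells of IsthUTJ and in secretory cells of InfAmp. Thinning weighs each cell alike, while the sums weigh cells by depth.

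For InfAmp against IsthUTJ, leaving out the block for the pool gave 2634 genes in ciliated cells (4156 with it), 1216 in secretory cells (4083) and 2 in fibroblasts (392). Where that left 2 genes in fibroblasts, 718 had an unadjusted p under 0.05. The DESeq2 Wald test gave 2159 in ciliated cells and 93 in fibroblasts, and the shared ciliated cluster alone 2298. Leaving out 1 library, without the block, gave 731 to 1902 genes in ciliated cells, 0 to 965 in secretory cells and 0 to 94 in fibroblasts. Where edgeR gave 0, 2222 and 2589 secretory genes and 586 and 782 fibroblast genes had an unadjusted p under 0.05. Of 48 named genes of the region comparison, 24 were no longer called by DESeq2 and 16 without the block, all in the same direction. Without vehicle InfAmp 37 named genes were no longer called and 10 still were, and without E2 InfAmp 36 and 9. Without vehicle IsthUTJ these were 12 and 25, and without E2 IsthUTJ 5 and 31. With no low-count filter 2466 ciliated genes were higher in InfAmp and 2149 lower, the other way round from 1892 and 2264. Without the block 647 secretory genes were higher and 569 lower, and 2 and 0 in fibroblasts, again the other way round. The balance also turned in mesothelial cells with doublets kept (365 and 354, from 247 and 350) and in smooth muscle with doublets kept (40 and 38, from 31 and 68) and without E2 IsthUTJ (74 and 57). In macrophages (91 and 147) it turned by DESeq2 (22 and 15), without the block (11 and 7) and without vehicle InfAmp (10 and 6) or E2 InfAmp (17 and 3). Counts of fewer than 20 genes in smooth muscle and mesothelial cells turned as well.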

Other observations

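The values in this part were looked at after the main comparisons, and no test was made on them for E2. In mesothelial cells Aqp5 was 132 CPM with vehicle and 1015 CPM with E2 in InfAmp (7.64-fold higher) and 131 and 1223 CPM in IsthUTJ (9.36-fold), and the Wnt receptor gene Fzd2 was 6.10-fold and 6.14-fold higher. Immediate early genes had medians of -1.96 and -1.81 over 17 genes, with 0 higher and 12 lower, the widest difference of any class. Atf3 was 508 and 52.1 CPM in InfAmp (9.68-fold lower) and 1307 and 137 CPM in IsthUTJ, and Fosb 5.99-fold and 4.12-fold lower. Heat shock genes, which also respond to handling, had medians of -0.355 and -0.365 over 14 genes, at percentile 0.0 of the random lists, as rounded, in both regions. Of them 0 were higher and 2 lower (Dnajb1 at -1.88 and -2.34, Hspa1a at -1.49 and -1.11). Uterine estrogen-induced genes were not high in both regions here: their medians were 0.38 in InfAmp and -0.03 in IsthUTJ over 16 genes. These stood at percentiles 100.0, as rounded, and 6.4 of the random lists. Of the 16 genes, 4 were higher, 3 lower (Klf4 and Sgk1 among them) and 9 neither. By the 2-fold rule 110 of 6645 genes were higher and 79 lower, and the median gene stood at 0.102 in IsthUTJ. That balance turned with cells thinned to 1000 UMIs (19 higher, 40 lower of 1477 measured) and with no low-count filter (476 and 596).

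In smooth muscle cells, the contracting layer, Inhbb was 12.4-fold and 7.92-fold higher with E2 and Gas1 4.09-fold and 4.12-fold lower. Uterine estrogen-induced genes had medians of 1.65 and 1.17 over 13 genes, with 7 higher and 0 lower. Contractility genes stood at -0.13 and -0.29, with none of 8 past the rule. Pgr was 309 and 569 CPM in InfAmp and 328 and 534 CPM in IsthUTJ. With cells thinned to 1000 UMIs it was 288.89 (13 UMIs) and 598.96 CPM in InfAmp and 248.91 and 473.68 CPM in IsthUTJ, so the InfAmp ratio stood on either side of 2-fold by the setting. By the rule 108 of 2668 genes were higher and 10 lower. In InfAmp the class held 502244 UMIs with E2 and 139382 with vehicle, so the measured level there favours genes high with E2. In IsthUTJ it held 599648 with E2 and 3465975 with vehicle, which there favours genes high with vehicle. With no low-count filter 803 were higher and 458 lower. The median gene stood at 0.147 in InfAmp, where vehicle had 50 cells.

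Macrophages had little Esr1. In them Mmp12, a macrophage elastase, was 6.14 and 615 CPM in InfAmp (84.1-fold, interval 27.5 to 830.3, from 2 vehicle UMIs) and 37.0 and 918 CPM in IsthUTJ (24.5-fold). Gpnmb, of lipid-laden macrophages, had 0 and 171 UMIs in InfAmp (at least 35.7-fold higher) and was 13.3-fold higher in IsthUTJ. Spp1, osteopontin, was 11.9-fold and 10.52-fold higher, and Cd36 and Lpl were higher too. By the rule 27 of 2183 genes were higher and 1 lower. Gdf15 was among those higher, and also in fibroblasts, secretory cells and smooth muscle. Macrophages of InfAmp held 520279 UMIs with E2 and 325580 with vehicle, so here too the measured level favours genes high with E2. With no low-count filter 657 were higher and 286 lower. The class held clusters 16 and 23: cluster 23 was 11.4% with vehicle and 9.2% with E2 in InfAmp, but 33.7% and 12.8% in IsthUTJ, and the genes were not compared inside a cluster. Retnla, of alternatively activated macrophages, was 289 and 769 CPM in InfAmp but 146 and 26.3 CPM in IsthUTJ.

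Between the regions, Hoxa10 had 0 UMIs in mesothelial cells of InfAmp and 53 in IsthUTJ (at least 4.65-fold, adjusted p 0.00106), and Ren1, renin, was 12.3 and 80.5 CPM. Hoxa10 in mesothelial cells stood at 13.8% of its level in its highest class. In smooth muscle Pcp4 was 4.68 CPM in InfAmp and 114 CPM in IsthUTJ from 3 InfAmp UMIs (24.5-fold, counting interval 8.32 to 119). The oxytocin receptor gene Oxtr was 14.0 and 49.2 CPM (log2 -2.42, SE 0.466) and the relaxin receptor gene Rxfp1 182 and 58.1 CPM (log2 2.06, SE 0.281). In macrophages Prg4 was 144 CPM in InfAmp and 0.80 CPM in IsthUTJ from 2 IsthUTJ UMIs (181-fold, counting interval 49.0 to 1511). At an adjusted p under 0.05, 597 genes differed in mesothelial cells, 99 in smooth muscle and 238 in macrophages. Without the block for the pool these were 0, 3 and 18 in edgeR, with 536 genes at an unadjusted p under 0.05 in mesothelial cells and 70 by DESeq2 with the block. DESeq2 gave 12 genes in smooth muscle and 37 in macrophages. Leaving out 1 library, without the block, gave 0 to 9 genes in mesothelial cells, 0 to 131 in smooth muscle and 16 to 453 in macrophages. Where edgeR gave 0, 467 and 426 mesothelial genes and 366 smooth muscle genes had an unadjusted p under 0.05. Macrophages had 633 genes with doublets kept and 110 at resolution 0.5. Ciliated markers were higher in InfAmp in 13 of 16, 7 of 11 and 11 of 11 genes of these classes (14, 10 and 11 adjusted over the list alone). Fibroblast markers were lower in macrophages in 6 of 7 (7 adjusted over the list alone), with a median of -4.64. Free RNA and doublets were not separated here.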
